A study of Drosophila melanogaster and Danio rerio with 21 samples.

How the data were processed

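Small RNA libraries were made from total RNA of fly eggs and embryos and zebrafish embryos. Per the labels' protocols, 10 µg of total RNA was size-selected on a gel at 15 to 29 nt (17 to 29 nt for the 4 libraries with synthetic RNA added), ligated to adaptors, reverse-transcribed, amplified and sequenced on HiSeq instruments. The submitters' processing notes name CASAVA, BWA, bedtools and edgeR and the builds dm3 and danRer7, without roles or versions. The miRNA annotation used is not given in the sources used here.

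The deposited miRNA table holds a signal that the authors scaled with TMM factors, per the file name; it is read here as library-size-scaled reads divided by those factors; column totals were 801061 to 1628309. Every value above 0 was a whole multiple of the smallest value of its column (100% of values, tolerance 1e-06), so that whole reads could be recovered, 2126216 to 12968026 per library or 65.1% to 82.3% of the miRNA reads in the class files. The deposited class files hold read counts per class and a percent, per the file headers; the percent equals the class's reads over all reads of the library, and libraries held 3220463 to 184054472 reads. How reads matching several classes were assigned is not given in the sources used here. The table column named for w1118 was taken as the 0-2 h egg, the only w1118 egg whose label names that table. All 12 sample columns were used.

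Each group had 1 library, so no replicate spread exists and p-values measure scatter between collection windows. SDs given for windows are over windows. Time course values were tested with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3 on log2(value + 1), with the log2 of the window midpoint in minutes as covariate, for the 135 miRNAs with a mean of at least 10 over the 10 windows; fold changes are on that scale, which understates changes of low miRNAs. p-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. 8 miRNA lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, which compares a list with the other miRNAs, with an estimated correlation and fry, which tests a list against no change, beside it, where at least 3 members passed the filter. edgeR 4.0.16 (quasi-likelihood) on the recovered reads, at the deposited scaling, was added after the data were seen and called 2 miRNAs by slope. The contrast of windows up to 120 min with later ones was set out in the design and is named in the results because it changes the calls.

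Eggs were compared by the log2 ratio of value + 1 for miRNAs whose mean in both libraries was at least 50, without a test. Counting intervals (95%) come from the exact binomial interval of the recovered reads; PCR reads carry no molecular identifiers, so intervals cover counting error alone. List medians were placed among 10000 random lists of the same size, matched in 4 bins of mean expression. Shares of reads have exact Clopper-Pearson 95% intervals. Class shares of early and late windows were compared by two-sided exact permutation of the libraries, adjusted over 11 classes. That comparison was not set out in the design, which named a correlation with age over the 10 windows. The miRNA shares of early and late windows fall in 2 separate ranges (13.6% to 20.4% and 28.7% to 32.7%), so a correlation with age over the 10 windows restates that step; it appears among the alternatives alone, and the results give the correlation within the 6 early windows, from exact permutation. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

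The time course tests were checked on simulated data for the 135 miRNAs with the depth of the real libraries and a dispersion of 0.05 (20 simulations). limma recovered 100% of slopes of 0.5 and of 1, with 4.02% false calls, and 100% of window changes of 1.5 and 3 log2, with 3.52% false calls. edgeR was run in the simulations with its own TMM factors and not at the deposited scaling used for the real data. It recovered 100% of the same changes, with 5.05% and 3.53% false calls. These shares hold for the simulated scatter and do not carry over to the real libraries. There limma called miR-7-3p (slope 0.59) and miR-3-3p (slope 0.50). It did not call miR-275-3p (slope -0.58, SE 0.16, limma adjusted p = 0.0632, edgeR adjusted p = 0.153). A slope that was not called is therefore not shown to be absent. The list percentile was outside 2.5 to 97.5 in 20 of 20 simulated lists shifted by 1 log2 and in 1 of 20 unchanged ones.

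Named miRNAs follow a rule fixed before the data were examined: up to 12 with the largest slopes in each direction among those past the threshold, the 12 highest and 12 lowest egg ratios, the 4 most abundant tested members of each list, and classes with at least 1% of reads in any library of the organism. miR-14-5p, miR-9b-3p, miR-306-3p, bantam-5p, miR-279-3p and the minor arms of the miR-309 cluster were named after their values were seen. Arms of near-identical copies (miR-6-1, miR-6-2 and miR-6-3; miR-2a and miR-2b; miR-13b; miR-276a and miR-276b; miR-281-1 and miR-281-2; miR-31a; members of the miR-310 family) can share reads, and their values are uncertain. No coordinates are given, because the reference used here is of another fly build than dm3. Alternatives covered pseudocounts of 0.1 and 10, filters, scaling to equal totals, median-ratio size factors, the coding of age, rank correlation and leaving out each window.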

Results

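Small RNAs were sequenced from fruit fly (Drosophila melanogaster) eggs and embryos and from zebrafish embryos to profile microRNAs (miRNAs) and their modification during early development. The 21 libraries comprised 17 from flies and 4 from zebrafish, and each condition had 1 library, so no value has a replicate error. A table of 374 mature fly miRNAs covered 12 libraries: unfertilized eggs of 0-2 h from the laboratory strain w1118 and from a mutant of wispy, the cytoplasmic poly(A) polymerase of the fly egg, and 10 collection windows of w1118 embryos from 0-15 min to 240-360 min. The other 9 libraries were a w1118 egg library of 0-3 h, 4 fly embryo libraries with added synthetic RNA and the 4 zebrafish libraries, for which read classes were used. Libraries held 3220463 to 184054472 reads, and the miRNA table rested on 2126216 to 12968026 reads per library. Modification of miRNA ends was not analysed here.

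The time course asked which miRNAs gain or lose abundance, in the TMM-normalised signal of miRNA reads, as the embryo passes from maternal to zygotic control. In the miR-309 cluster, a zygotic polycistron whose miRNAs promote clearance of maternal mRNAs, miR-286-3p rose from a TMM-normalised signal of 95577 at 0-15 min to 351457 at 240-360 min, with a peak of 495104 at 90-120 min and 300969 at 120-150 min. Its slope was 0.45 log2 units per doubling of age (SE 0.08, limma adjusted p = 0.00984). Its cluster neighbour miR-3-3p also rose, with a slope of 0.50 (SE 0.11, limma adjusted p = 0.0493), but its adjusted p ran from 0.00183 to 0.604 over the alternatives. Its call was lost by edgeR (edgeR adjusted p = 0.0991) and when any 1 window other than 90-120 or 240-360 min was left out. miR-7-3p, the minor arm of a miRNA with roles in photoreceptor differentiation, rose from 32.0 to 209 with a slope of 0.59 (SE 0.09, limma adjusted p = 0.00730). These 3 of the 135 miRNAs tested were the ones that rose, and the slope test called 0 falling, although 35 miRNAs had a negative and 15 a positive slope at an unadjusted p under 0.05. edgeR on the recovered reads called 2 rising, miR-286-3p and miR-7-3p, and 0 falling. The slope is sensitive to how age and scale enter: 13 rose and 35 fell with every library set to the same total, and 12 rose and 21 fell without the 90-120 min library. Without the 0-15 min library 1 miRNA rose, miR-7-3p, and the adjusted p of miR-286-3p became 0.0611.

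A contrast of the 6 windows up to 120 min with the 4 later ones was an alternative to the slope test. It gave 36 higher and 45 lower miRNAs, with the median miRNA shifted by 0.32 log2. edgeR on the same contrast called 18 higher and 43 lower, all among the limma calls. The members of the ovary-enriched and maternal list made up much of the lower side, with 21 of 30 lower and 3 higher later (20 and 1 by edgeR). With every library set to the same total, 19 of these members were lower and 6 higher. miR-312-3p went from 164388 ± 33979 (SD, n = 6 windows) to 43744 ± 13294 (SD, n = 4 windows), a log2 change of -1.92 (SE 0.22, limma adjusted p = 9.44e-05). miR-995-3p went from 109116 ± 11937 to 45440 ± 7239 (log2 change -1.27, SE 0.14). miR-184-3p, needed in female germline development, and bantam-3p, a growth regulator that blocks cell death, went from 94777 ± 9337 to 47446 ± 4467 and from 101327 ± 5405 to 59251 ± 10824. Both were lower later, with limma adjusted p = 9.44e-05 and 0.000531. The signal is scaled by TMM factors, and its total differs between libraries (1.62831e+06 at 90-120 min, 801061 at 150-180 min). The miRNA share of all reads was 1.74-fold higher after 120 min. In this signal bantam-3p was 1.73-fold, miR-184-3p 2.00-fold and miR-312-3p 3.80-fold lower. These folds are not folds per miRNA read, so they cannot be set against the change of that share. Whether these miRNAs fell among all reads was not tested. On the slope over all 10 windows 24 of the 30 members were negative and 0 passed over all miRNAs. When adjusted over the list alone, 11 fell and 1 rose. The list stood below other miRNAs by camera (adjusted p = 0.000534), which was lost with an estimated correlation (adjusted p = 0.393).

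The miR-310 family, clustered miRNAs of the female germ line and testis, was lower later in 7 of its 8 tested members by the contrast of windows (6 by edgeR). Of these 8 members 7 also belong to the ovary-enriched and maternal list, so the 2 lists are not separate results. miR-311-3p went from 90696 ± 16895 to 26691 ± 7561 and miR-310-3p from 11752 ± 2289 to 3257 ± 1069. miR-313-3p changed by -1.38 log2 (SE 0.33, limma adjusted p = 0.00574). By slope 0 members passed over all miRNAs, while 6 fell and 1 rose when adjusted over the list alone. Camera gave an adjusted p = 0.0136, and an estimated correlation an adjusted p = 0.393. Of 6 mirtrons, miRNAs cut from spliced introns, 4 were lower later, among them miR-1010-3p (-1.09 log2, SE 0.17), miR-1003-3p (-0.91, SE 0.21) and miR-1012-3p (-1.70, SE 0.22). miR-1013-3p, with 22.3 before and 24.1 after 120 min, did not pass. Mirtron slopes were negative in 6 of 6 members (0 passed, also when adjusted over the list alone; camera adjusted p = 0.0407, and adjusted p = 0.393 with an estimated correlation). With every library set to the same total the camera adjusted p of the mirtrons was 0.0730. On the contrast of windows the mirtrons did not pass camera (adjusted p = 0.0636, and 0.422 with an estimated correlation).

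The miR-309 cluster behaved differently from a step at 120 min. Of its 14 arms 13 had positive slopes, 2 rose over all miRNAs and 6 when adjusted over the list alone, and camera placed the list above other miRNAs (adjusted p = 0.000534, and adjusted p = 0.393 with an estimated correlation). Without the 0-15 and 15-30 min windows 7 arms had positive and 7 negative slopes, and 1, miR-286-3p, rose. In the contrast of windows 0 of 14 passed, with a median of -0.06 log2 that became 0.26 with every library set to the same total, where 5 passed. miR-6-3p stood at 10784 at 0-15 min, 32163 at 90-120 min and 28876 at 240-360 min. miR-4-3p stood at 6058, 30330 and 12863 in the same windows. miR-6-3-5p, the other arm of a miR-6 hairpin, reached 42118 at 90-120 min and was 143 at 240-360 min.

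miRNAs of embryonic muscle, the Hox loci and the nervous system were higher after 120 min in 7 of 11 tested list members and lower in 2 (5 and 2 by edgeR). By camera on this contrast the list did not pass (adjusted p = 0.175, and 0.602 with an estimated correlation). miR-10-5p, encoded in a Hox cluster, went from 18678 ± 8004 to 33850 ± 8595 (log2 change 0.92, SE 0.30, limma adjusted p = 0.0274), and its other arm miR-10-3p changed by 1.04 (SE 0.35). miR-92a-3p was lower, by -1.27 log2 (SE 0.17). The muscle miRNA miR-1-3p averaged 12449 ± 5876 and then 21725 ± 9093 and did not pass (limma adjusted p = 0.0786). By slope 9 of 11 were positive and 1 rose, both over all miRNAs and adjusted over the list alone (camera adjusted p = 0.0407, adjusted p = 0.393 with an estimated correlation, and 0.0836 by camera with every library set to the same total). In this list and the next, members had high values in the earliest collections: miR-1-3p read 16427 at 0-15 min and 21510 at 15-30 min against 6844 at 30-45 min, and miR-276a-3p read 15832 and 25021 against 4774. Leaving out those 2 windows, a step chosen after seeing the data, raised the slope calls to 52 rising and 35 falling. miR-10-5p and miR-1-3p then had slopes of 0.68 (SE 0.13) and 0.77 (SE 0.12), against 0.29 and 0.15 over all 10 windows. Dropping high early values raises a slope by construction, so these slopes do not test a rise.

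Among markers of late or adult tissue, 3 of 8 tested members were higher and 2 lower after 120 min, against 1 and 2 by edgeR. miR-276a-3p changed by 1.62 log2 (SE 0.54) and miR-277-3p by 2.30 (SE 0.60), and miR-276b-3p went from 358 ± 349 to 731 ± 143, while miR-281-2-5p changed by -0.99 (SE 0.18). Of 9 tested members of the miR-2, miR-13 and miR-11 K-box group, miRNAs that repress proapoptotic genes, 5 were lower and 1 higher (5 and 0 by edgeR). With every library set to the same total, 4 K-box members were lower and 3 higher. That setting gave 1 lower and 3 higher adult-tissue members, and 1 lower and 8 higher patterning members. It gave 6 lower members in the miR-310 family and 3 in the mirtrons, with 0 higher in both. miR-11-3p changed by -0.82 (SE 0.12), miR-13b-3p by -0.96 (SE 0.17) and miR-2b-3p by -0.66 (SE 0.14), and miR-11-5p by 0.85 (SE 0.33). edgeR did not call miR-276a-3p, miR-276b-3p or miR-11-5p (edgeR adjusted p = 0.0912, 0.173 and 0.109). By slope neither list passed camera (adjusted p = 0.580 and 0.496), and 0 and 1 members, the latter rising, passed when adjusted over the list alone. Of the testis-enriched list 1 member, miR-983-5p, passed the filter, so the list was not tested. It stood at 14.8 ± 1.14 before and 8.80 ± 4.28 after 120 min (limma adjusted p = 0.0325, edgeR adjusted p = 0.0694).

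**Figure D1:**
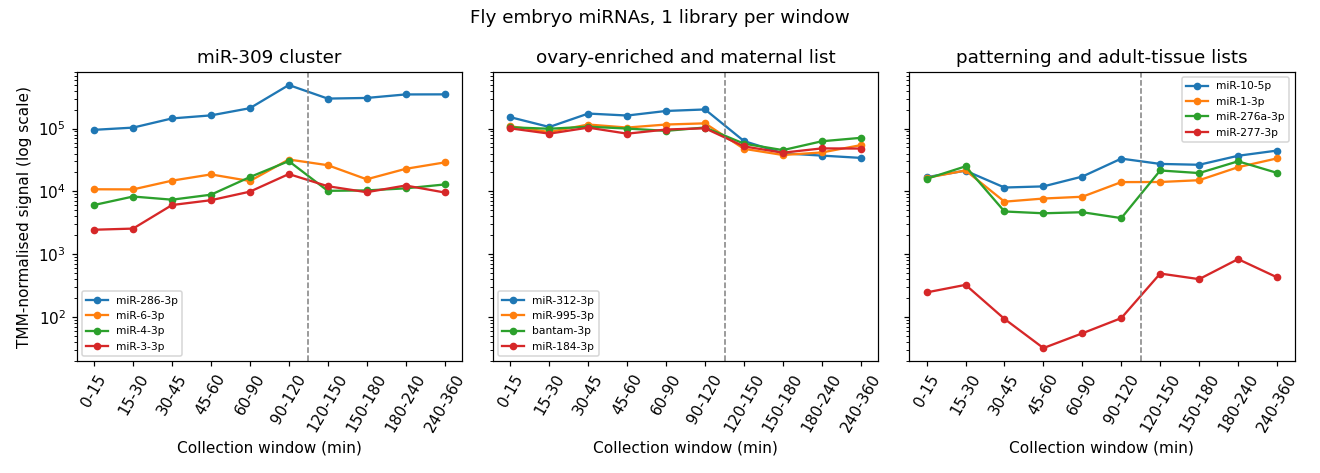
Abundance of 12 fly miRNAs (TMM-normalised signal, log axis) in the 10 embryo collection windows, with 1 library per point and the dashed line at 120 min. The maternal list members lie lower after the line (miR-312-3p 164388 before and 43744 after on average), miR-286-3p goes from 95577 to a peak of 495104 at 90-120 min and stands at 351457 in the last window, and miR-1-3p and miR-276a-3p dip after the first 2 windows.

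To compare the maternal supply with embryos, the w1118 library of unfertilized eggs of 0-2 h was set against the 6 embryo libraries of the same span. Whether that egg library was free of embryo RNA is left open. All 14 tested arms of the miR-309 cluster lay below the embryo range. miR-286-3p was 35101 in eggs and 202270 ± 149513 (SD, n = 6 windows) in embryos, 5.76-fold higher in embryos, and miR-6-3p was 2370 against 16949 ± 8012. Patterning miRNAs were below it in 6 of 10 members and above it in 2, miR-7-5p and miR-92a-3p, with miR-10-5p at 5140 against a lowest embryo value of 11500 and miR-1-3p at 3980 against 6844. Maternal-list members lay above it in 14 of 29 and below it in 5. miR-995-3p was 215145 in eggs against 109116 ± 11937 in embryos, bantam-3p 190577 against 101327 ± 5405 and miR-311-3p 200169 against 90696 ± 16895. In the miR-310 family 5 of 8 lay above and 2 below, in the K-box group 5 of 9 above and 3 below, in the mirtrons 4 of 6 above and 0 below, and in the adult-tissue list 2 of 8 on each side. With every library set to the same total, 2 mirtrons, 1 patterning miRNA, 12 maternal-list and 4 K-box members were above, 7 patterning and 6 maternal-list members below, and 1 adult-tissue miRNA on each side. The testis miRNA miR-983-5p was above the embryo range at 38.0 against 14.8 ± 1.14. Of 131 miRNAs, 41 (31.3%) were above and 49 (37.4%) below all 6 embryo libraries, where chance gives 14.3% on each side, and 32 and 53 with every library set to the same total. These signals are miRNA reads scaled by TMM factors, and miRNA reads were 8.52% of all reads in this egg library and 17.4% ± 2.31 in the 6 embryo libraries. A higher signal in eggs thus does not show more of a miRNA among all reads. With 1 egg library the comparison has no test.

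Eggs of the wispy mutant were compared with w1118 eggs because Wispy adds adenosines to RNA in the egg. The largest ratio was that of miR-311-5p, at 898 in the mutant and 13.5 in w1118, 66.5-fold higher (95% counting interval 43.4 to 108). miR-9b-5p was 10.2-fold higher (8.48 to 12.3), miR-14-3p 3.47-fold (3.44 to 3.50), and miR-92b-3p 2.61-fold, at 102387 against 39208. miR-7-5p, miR-305-3p and miR-33-5p completed the 7 miRNAs at least 2-fold higher on the scale of log2(value + 1), at 2.26-, 2.06- and 2.01-fold without the added 1. miR-275-5p, miR-2b-3p, miR-11-3p, miR-313-5p and miR-312-3p followed, with log2 ratios of 0.99, 0.87, 0.84, 0.77 and 0.66. With a pseudocount of 0.1, 8 miRNAs were at least 2-fold higher. The lower side was larger in this signal, with 28 of 82 miRNAs at least 2-fold lower in the mutant. miRNA reads were 18.4% of all reads in the mutant library and 8.52% in the w1118 library. Among all reads each ratio would stand higher, so the counts on the 2 sides hold for the scaled miRNA signal alone. miR-956-3p was 20.8-fold lower (13.9 to 32.3), miR-958-3p 15.1-fold, miR-277-3p 15.0-fold and miR-133-3p 11.7-fold. The muscle miRNA miR-1-3p was 373 against 3980, 10.7-fold lower (10.0 to 11.4), and miR-276a-3p was 440 against 4614, 10.5-fold lower. miR-31a-5p, miR-263a-5p, miR-10-3p, miR-4-3p, miR-276b-3p and miR-10-5p were 9.41-, 9.35-, 9.27-, 9.04-, 9.02- and 8.14-fold lower.

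By list, all 8 tested members of the miR-309 cluster were at least 2-fold lower in the wispy mutant, with a median log2 ratio of -2.60. miR-286-3p was 6387 against 35101, 5.50-fold lower, and miR-6-3p and miR-3-3p were 6.12- and 5.50-fold lower. That median stood at percentile 3.62 of random lists of the same size matched on mean expression, a description of these 2 libraries. Patterning miRNAs had a median of -2.72 (percentile 1.20), with 5 of 8 lower and miR-7-5p higher, while miR-92a-3p was at -0.21. In the 6 patterning members with a mean of at least 500 the median was -1.62 (percentile 23.6). With a pseudocount of 10 the percentile was 3.015. Adult-tissue miRNAs had a median of -3.10 (percentile 2.57), with miR-276a-3p, miR-276b-3p and miR-277-3p lower and miR-281-2-5p at 0.06. The ovary-enriched and maternal list had a median of 0.34 (percentile 99.9), with 18 of 25 members within 2-fold, 5 higher and 2 lower. With both libraries set to the same total its median was 0.12, with 4 higher and 4 lower, and with a mean of at least 500 its percentile was 90.9. Of its abundant members, miR-995-3p was 217746 against 215145 and bantam-3p 154648 against 190577, while miR-14-3p and miR-92b-3p were among the 5 higher. The miR-310 family had a median of 0.54 (percentile 96.5), with 6 of 7 within 2-fold. miR-312-3p was 356509 against 225936 and miR-310-3p 22856 against 27423. The K-box group (7 members, median -0.04, percentile 73.0) and the mirtrons (4 members, median -0.06, percentile 83.0) held no member beyond 2-fold. Setting the median ratio to 0 shifts all miRNAs alike, and so turned those 2 small medians positive (0.24 and 0.23). The miR-310 family median became -0.24 (percentile 29.1) in the 5 members with a mean of at least 500. Of the 7 miR-310 family members all are also in the ovary-enriched and maternal list. Ratios are relative to a median of -0.28 over the 82 miRNAs, which was -0.50 with both libraries set to the same total, where 4 miRNAs were higher and 30 lower. There is no replicate check, the intervals cover counting error alone, and the wispy transcript is not measured by these libraries, so the genotype label was not checked.

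**Figure D2:**
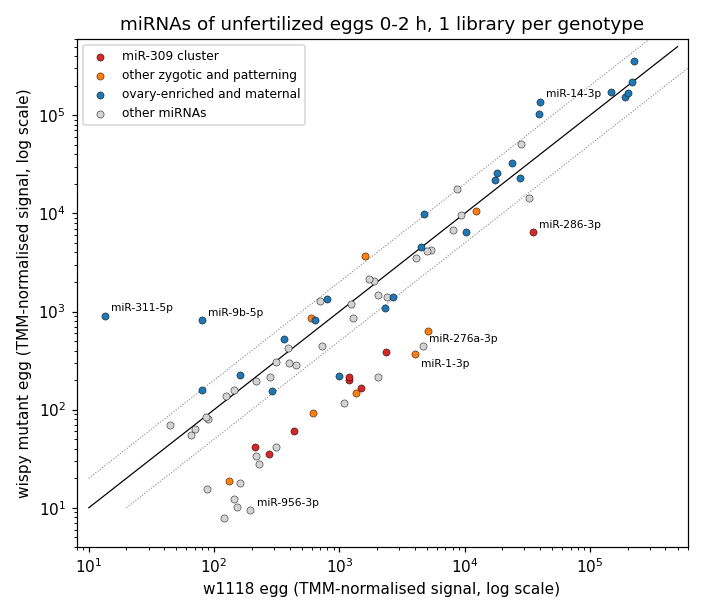
Each point is 1 of 82 miRNAs, with its value in the w1118 egg library on the horizontal and in the wispy mutant egg library on the vertical axis (TMM-normalised signal, log axes); the solid line marks equality and the dotted lines a 2-fold difference. The miR-309 cluster lies below the lower dotted line in 8 of 8 members, and miR-311-5p (898 against 13.5) lies farthest above.

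miRNAs with a lower ratio in the mutant eggs tended to have a more positive slope with embryo age. Across 81 miRNAs, Spearman's rho between the wispy to w1118 log2 ratio and the slope with embryo age was -0.59 and Pearson's r was -0.68. With the contrast of windows at 120 min in place of the slope, rho was -0.60 and r was -0.71. miR-286-3p had a ratio of -2.46 and a slope of 0.45, and miR-312-3p a ratio of 0.66 and a slope of -0.43. The relation has exceptions: miR-279-3p had a ratio of -1.19 and a slope of -0.33, and miR-31a-5p a ratio of -3.22 and a slope of 0.00284. The correlations run across miRNAs, which are not independent replicates, and rest on 1 egg library per genotype, so no p-value is given.

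Read classes in the 10 windows showed a gain of miRNA reads after 120 min. miRNA held 17.4% ± 2.31 (SD, n = 6 windows) of reads in embryos up to 120 min and 30.4% ± 1.71 (SD, n = 4 windows) later, with every later window above every earlier one. The two-sided exact permutation p was 0.00952, the smallest that 6 against 4 can give, and 0.0262 after adjustment over 11 classes. This comparison was not set out in the design, and ranges that do not overlap give that smallest p by construction. The planned correlation with age over the 10 windows is given among the alternatives. Transposon-derived reads were lower later by the same test: LINE fell from 6.24% ± 0.994 to 3.61% ± 0.581, LTR from 6.01% ± 0.873 to 3.44% ± 0.600 and DNA transposons from 1.12% ± 0.172 to 0.652% ± 0.0632 (exact adjusted p = 0.0262 each). Intronic reads fell from 1.19% to 0.897% and unannotated reads from 1.78% to 1.16% (exact adjusted p = 0.0349 each). A larger miRNA share lowers the shares of other classes, so part of these falls restates it. rRNA, the largest class in these 10 windows, held 53.6% ± 4.70 and 48.2% ± 2.64 and did not pass (exact adjusted p = 0.0748). tRNA (1.00% and 0.976%), ORF (1.53% and 1.29%), UTR3 (0.409% and 0.392%) and unmapped reads (9.13% and 8.51%) did not pass either. Within the 6 early windows the miRNA share had a Spearman rho of -0.31 with age (exact permutation p = 0.564, adjusted p = 0.620) and a Pearson r of -0.21 (exact permutation p = 0.678, adjusted p = 0.746). Without the 2 windows farthest from the median age, r was -0.42.

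Among eggs, miRNA was 8.52% of reads in w1118 at 0-2 h (95% Clopper-Pearson interval 8.51 to 8.53), 18.4% in the wispy mutant and 17.7% in w1118 at 0-3 h. rRNA took 73.6%, 61.6% and 48.5% of the same libraries, LINE 3.64%, 3.51% and 7.71%, and LTR 3.42%, 3.18% and 5.63%. In the 4 embryo libraries with added synthetic RNA, miRNA was 33.6% at 0-1 h, 36.7% at 2-3 h, 46.0% at 5-6 h and 31.0% at 11-12 h. Their rRNA shares were 37.1%, 39.2%, 32.3% and 41.1%, and LINE went from 4.86% at 0-1 h to 1.21% at 11-12 h. The 11-12 h library also had 3.74% tRNA and 1.51% UTR3 reads. The class files list no spike-in class, so miRNA reads per spike-in read were not computed. These libraries held 3220463 to 4961434 reads.

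**Figure D3:**
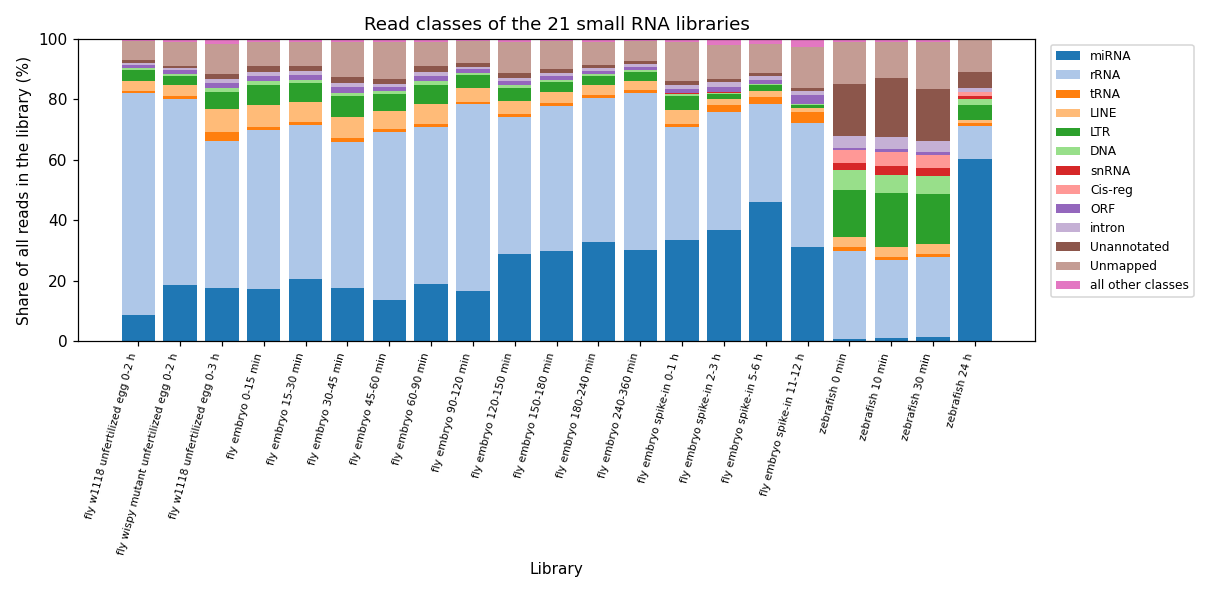
Stacked bars give the share of reads (percent of all reads in a library, axis from 0) per class in the 21 libraries, 1 bar per library. The miRNA part is 8.52% to 46.0% in flies and goes from 0.745% to 60.3% between the first and last zebrafish library.

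Early zebrafish embryos held few miRNA reads. The miRNA share was 0.745% at 0 min (0.743 to 0.747), 0.882% at 10 min and 1.29% at 30 min, and 60.3% at 24 h, 80.9-fold that at 0 min. LTR reads went from 15.6% at 0 min to 4.93% at 24 h and DNA transposon reads from 6.54% to 2.05%. LINE went from 3.34% to 0.905%, rRNA from 29.1% to 10.9% and unannotated reads from 17.0% to 5.34%. snRNA went from 2.41% to 0.819%, Cis-reg, a class of cis-regulatory RNA elements, from 4.20% to 1.26%, intron from 4.01% to 1.23% and unmapped reads from 14.1% to 10.4%. tRNA was 1.13% in both libraries. The larger miRNA share alone would bring other classes to 0.400 of their share at 0 min, so most of these differences restate it. The fold of the miRNA share was 64.4 with rRNA left out of the total. With 1 library per time the differences have no test beyond their counting intervals.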

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

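edgeR and the settings without the 2 earliest windows were chosen after seeing the data. The cause of the differences below was not tested, except where fewer miRNAs or libraries enter. Rising and falling miRNAs (3 and 0) became 7 and 2 with a mean of at least 100, 13 and 35 with equal totals, 12 and 32 with the rank of the window, 6 and 2 by Spearman correlation, and 36 and 45 by windows around 120 min. Rising fell to 1 without a filter and to 1 with median-ratio size factors, with 0 falling in both. Leaving out 1 window gave 1 to 12 rising (1 without 0-15 min, 12 without 90-120 min) and 0 to 21 falling (21 without 90-120 min, 0 without any other window). Without 0-15 and 15-30 min the slope called 52 and 35, and the windows 53 and 45. edgeR called 18 and 43 by windows. Pseudocounts of 0.1 and 10 and edgeR's slope gave 2 or 3 rising and 0 falling.

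The 5 lists passing camera became 0 with an estimated correlation and 3 with equal totals. fry, which tests a list against no change and not against other miRNAs, called 1, the maternal list, but 0 with a mean of at least 100 and 4 with equal totals. Wispy eggs had 7 miRNAs higher and 28 lower: 4 were higher with equal totals and 11 with the median set to 0, while 48 were lower with a mean of at least 10 and 14 with a mean of at least 500. The 2 lists with a median outside the central 95% of random lists became 0 with a mean of at least 500. Eggs outside the embryo range went from 90 miRNAs to 59 with a mean of at least 100. The ratio and slope relation kept its sign and size in both alternatives.

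The median miRNA share of fly libraries, 20.4%, became 48.0% without rRNA and 22.6% without unannotated or unmapped reads. The zebrafish fold of 80.9 became 64.4 and 66.2. The rank correlation of miRNA share with age over the 10 windows, which restates the step at 120 min, lay with 1 window left out between 0.600 (without 120-150 or 150-180 min) and 0.817 (without 90-120 min), from 0.709, with a permutation p above 0.05 without any 1 of the 4 later windows. Of the counts and summary values, 49 alternatives stayed within 1.5 times or on their side of the threshold, 34 moved and 4 lost a call. For single miRNAs and lists, 660 values stayed on their side of the threshold or within error, 73 moved, 124 gained and 33 lost a call. No value past its threshold changed sign in these alternatives, while several uncalled values did, among them the egg medians of the miR-310 family, K-box group and mirtrons, the window median of the miR-309 cluster and the median slope of the adult-tissue list (-0.04, and 0.10 with a mean of at least 100). Spike-in alternatives were not run, as the class files list no spike-in class. No paired analysis was possible because no group has more than 1 library.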

Other observations

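All tests in this part were chosen after the results were seen. The arms of the miR-309 cluster separated with age. miR-6-3-5p went from 42118 of TMM-normalised signal at 90-120 min to 143 at 240-360 min, while miR-6-3p went from 32163 to 28876. miR-6-1-5p went from 19912 to 52.5, miR-286-5p from 12577 to 397 and miR-3-5p from 75.2 to 0.354. As a share of its major arm, miR-286-5p was 2.54% at 90-120 min and 0.113% at 240-360 min. This ratio lies within 1 library and is not moved by scaling. It was 6.53- to 340-fold lower in 6 of the 8 hairpins of the cluster, more than in any of 32 other hairpins (highest 3.41-fold). The exceptions were miR-5 (1.20-fold) and miR-309, whose 3p arm was 13.7% of the 5p arm and then 90.7%. Reads of the 3 miR-6 copies can be shared.

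Outside the cluster the minor arm took a higher share at 240-360 than at 90-120 min in 23 of 32 hairpins and a lower one in 9. Of the 13 of these in the ovary-enriched and maternal list, 9 were higher and 4 lower. bantam-5p was 3.41% of bantam-3p at 90-120 min and 13.8% at 240-360 min, miR-14-5p 3.06% and 23.5% of miR-14-3p (19.9% at 15-30 min), and miR-306-3p 1.47% and 4.54% of miR-306-5p. miR-313-5p went from 47.9% to 14.0% of miR-313-3p. In eggs, miR-14-5p was 2.51% of miR-14-3p in w1118 and 0.158% in the wispy mutant. miR-9b-5p was 18.0% of miR-9b-3p in the mutant and 1.80% in w1118, against at least 11.2% in each of the 10 embryo windows. miR-311-5p, at 898 in the mutant and 13.5 in w1118 eggs, was 0.232 to 1.02 in the embryo windows.

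Of 135 miRNAs, 46 were at least 2-fold higher at 0-15 and 15-30 min than in the next 4 windows, with a median log2 of 1.77. The authors' scaling as the whole source is argued against: it applies 1 factor per library to every miRNA, and the ovary-enriched and maternal list had a median log2 of -0.20 in the same ratio (30 members, quartiles -0.39 and 0.14). Embryos of 240-360 min as the whole source are argued against too: the median share needed, 72.0% (lower quartile 51.7%), would bring the miR-309 cluster to 31.5% of miRNA reads (lower quartile 22.6%), and 11.9% and 14.7% were read. RNA of older embryos, such as eggs retained before laying, may be present but is not shown. With no library shared, the early excess and the 240-360 min excess correlated across miRNAs (Spearman rho 0.779). Both ratios divide by windows of the same dip (30 to 60 and 60 to 120 min), so this rho does not tell sources apart. Loss of inherited miRNAs by 30 min cannot be told apart from RNA of older embryos, with 1 egg library per genotype. The w1118 egg held 0.554 of the level expected if eggs followed embryos (quartiles 0.361 and 0.911). The wispy egg held 0.0590 (quartiles 0.0456 and 0.122), which goes against inheritance but comes from mutant mothers.

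Of 16 zygotic miRNAs in the miR-309 cluster and patterning lists, 13 were at least 2-fold lower in wispy than w1118 eggs. Scaling as the whole source is argued against: the 16 had a median log2 ratio of -2.66, while the ovary-enriched and maternal list had 0.34 (25 members, quartiles -0.26 and 0.77). RNA of developing embryos in the w1118 egg library is a candidate source: the ratio correlated with the 240-360 min excess over 30 to 120 min (Spearman rho -0.548 across 81 miRNAs), and 16 of the 28 lower miRNAs were also high in the 2 earliest embryo windows, where 6.49 would overlap by chance. Loss of Wispy cannot be told apart from it, with 1 library per genotype.

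The calls of the time course were also counted under other groupings of the 10 libraries. For windows around 120 min, 1 of 100 splits (the real one, 81 calls) was as large and the highest other gave 57. This argues against an arbitrary grouping of the libraries as the source of that count. A cut in time order can exceed mixed splits under any drift between libraries, so the count does not tell an effect of age from drift. For the slope, 4 of 100 orders had at least the real 3 calls, but the highest other order gave 78, which points to a structure of the libraries. Where that structure lies is not settled. Without the 2 earliest windows the slope called 52 rising and 35 falling, but dropping high early values raises a slope by construction. Without the 90-120 min window alone it called 12 rising and 21 falling. The highest other split of windows, with 57 calls, placed 15-30 min with 150-180, 180-240 and 240-360 min. Which order gave 78 was not recorded.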
